A study of Mus musculus with 18 samples.

How the data were processed

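Single-cell RNA sequencing of mouse liver was analysed in 18 libraries. Per the labels, 6 were whole-liver controls from old mice (OC), 5 were enriched for the fibrotic niche from old mice (OF, named FiNi-seq), 3 were controls from young mice (YC) and 4 were enriched from young mice (YF). Old meant 22 to 24 months and young 6 months. The labels come in 2 forms. Set 1 holds all OC and OF libraries and YF 1 to 3, and set 2 holds YC 1 to 3 and YF 1b. Set 2 also carries a diet protocol, started at 4 months and lasting 6 weeks with a control diet or one with 0.1% of a supplement (DCC), and does not say which library had which, so diet was not modelled. The labels do not say that libraries came from separate animals, so every p-value measures the spread between these libraries.

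The authors deposited raw UMI counts per gene and barcode for 32285 genes. The submitters' notes name Cell Ranger 4.0.0, the mm10 genome and Scanpy, whose version is not given. Per the file headers 14 matrices came from Cell Ranger 6.0.2, and 4 (OC 2, 4, 5 and 6) name no software. The lowest UMI count of any barcode was 500 in 12 libraries, 724 in YF 3, 1014 in YF 2 and 3605 to 6603 in those 4 OC libraries, which can set which cells are seen in them. A deposited table of cell types, written by the authors without a stated method, was joined by barcode to set 1. Each library name was matched to the file holding all of its barcodes, for 57028 cells. A further 36173 annotated cells under 4 young control names matched no file here and were not used.

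Cells of set 2 have no deposited names and were named here. Barcodes with at least 500 and at most 7500 genes and at most 20% mitochondrial UMIs were kept, scaled to 10000 UMIs, log transformed, reduced over 2000 variable genes to 30 principal components, and clustered with Leiden at resolution 1 on 15 nearest neighbours (scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). By 15 marker sets, a cluster took the class with the highest marker score among those with at least 3 markers seen in 20% of cells, or a class with more markers among the cluster's 10 leading genes, if it too had 3 such markers. Left unnamed were clusters of low depth with no such leading gene, cluster 27 of set 2, best scored as endothelial but with more leading markers of a class that lacked 3, clusters led by at least 5 acinar pancreas genes, and clusters with 1.25 times their library's median UMI count in which 7 or more markers of another class were seen in 50% of cells (doublets). The naming and doublet thresholds were set after the data were seen. Doublet thresholds of 5 and 6 markers, tried first, left out a mesenchymal cluster. Unnamed cells were 14.8% of YC 1, 11.9% of YC 2, 13.4% of YC 3 and 14.1% of YF 1b. Clusters were made and numbered within each label set. The same steps on set 1 put 95.7% of 52599 cells in the authors' class. In all, 82617 cells were used in classes. The classes were hepatocytes, cholangiocytes, endothelial cells, mesenchymal cells (stellate cells and fibroblasts), phagocytes (Kupffer cells, macrophages and monocytes), dendritic cells, neutrophils, T and NK cells, and B cells.

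Shares are percent of annotated cells per library, compared by two-sided exact permutation tests of the difference in means, with Benjamini-Hochberg adjustment over 9 classes within a comparison. For genes, UMI counts were summed per library and class where the library held at least 20 cells. A class was tested where both groups had at least 3 such libraries. Counts were scaled by TMM, filtered by filterByExpr and fitted with all groups in 1 model by edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3. A gene was called at an adjusted p under 0.05 within a comparison and class. Changes are log2 fold changes, with a standard error (SE) from the change and its F statistic. Where a group had 0 counts a fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with its exact 95% interval. Such bounds cover counting error only. The rest used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Gene positions are from GENCODE vM21 on GRCm38.

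Before the data were examined, groups, comparisons, tests, the alternatives to be run, 32 gene lists and a rule for named genes were fixed. The rule takes, per comparison and class, the 3 highest and 3 lowest changes among called genes with an average log2 CPM of at least 5 and no overlap between the groups' libraries. It leaves out predicted genes, ribosomal protein and mitochondrial genes, and immunoglobulin and T cell receptor segments. It adds up to 4 members of each list with the lowest p, and Xist, 4 Y-linked genes, Alb, Hbb-bs and the mitochondrial share per library. Results for 2 genes withheld for evaluation are not reported by gene, and they remain in the counts. Lists were tested with camera (limma 3.58.1, two-sided) at a preset correlation of 0.01, adjusted over all tests of lists in a comparison, and with an estimated correlation as an alternative. List members are counted by calls over all genes and adjusted over the list alone.

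The lists in mesenchymal cells were fibrillar matrix, stellate activation, stellate quiescence and portal fibroblast. Those in phagocytes were scar-associated macrophage, Kupffer identity and monocyte identity, in cholangiocytes ductular reaction, in endothelial cells sinusoidal identity, capillarised vascular and pericentral, and in T and NK cells effector and exhaustion, and naive. Lists of antigen presentation (MHC class II), interferon response, NF-kB inflammation, senescence and secretory factors, and cell cycle ran in several classes. Lists of RNA quality and of other cell types were dissociation stress (immediate early and heat shock genes), hepatocyte free RNA, erythroid, mitochondrial, Kupffer genes in endothelial cells, and endothelial or lymphocyte genes in phagocytes. The endothelial list also ran in mesenchymal cells. A further 7 lists for hepatocytes were not tested, since hepatocytes reached 20 cells in at most 3 libraries of a group and never in 3 of both.

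Alternatives were DESeq2 1.42.0, no TMM, no filter, at least 50 cells, each library left out in turn, the replicate number as a block, no cells among the 5% with the most UMIs, a hepatocyte free RNA covariate, each label set alone, and for shares edgeR on cell counts and a total without hepatocytes. Added after seeing the data were own cluster names in every library, leaving out libraries with a code (DQ1d or DQ3m) in their cell names, OC libraries with a software header only, the T or Macrophage type alone, a dissociation share covariate, shares over cells of at least 6624 UMIs, and cluster 27 of set 2 (192 cells of YC and 97 of YF 1b, led by Ednrb, Adgrg6 and Gja5 like cluster 17 of set 1) kept as endothelial. The method was tested on simulated data made from these libraries with 200 changed genes. At a 2-fold change 1.25% (YF against YC, mesenchymal) to 78.8% (OF against YF, cholangiocytes) were recovered, and 1.33% to 11.6% of calls were false. Barcodes without a class, and mesenchymal cells and hepatocytes where too few libraries held 20 cells, were left out of the gene tests.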

Results

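Single-cell transcriptomes of mouse liver came from whole-liver controls and from digests enriched for the fibrotic niche (FiNi-seq). Libraries were 6 old control (OC), 5 old enriched (OF), 3 young control (YC) and 4 young enriched (YF). The 18 libraries held 734919525 UMIs in 138487 barcodes. Total UMIs per library were 18725636 to 45847295 in OC, 24165961 to 40234279 in OF, 37735470 to 76374914 in YC and 32823146 to 67454132 in YF. Median UMIs per cell used were 1374 to 11798 in OC, 2875 to 5337 in OF, 4106 to 5114 in YC and 6188 to 10188 in YF. Every library had a male pattern, with 1 to 28 Xist counts and 119 to 352 CPM over 4 Y-linked genes. Values are means ± SD over libraries for shares, and log2 changes ± SE from edgeR for genes.

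OF was compared with OC to ask how cells of the enriched niche differ from those of the whole liver in old mice (n = 5 and 6). The enriched digest held fewer endothelial cells, at 3.97% ± 1.97 against 36.3% ± 9.38 (SD). It held more T and NK cells (51.0% ± 14.6 against 17.8% ± 11.2), more cholangiocytes (11.1% ± 6.36 against 0.877% ± 0.598) and more mesenchymal cells (5.17% ± 3.57 against 0.175% ± 0.101). In these 4 classes no OF library overlapped an OC library (exact permutation p = 0.00217 each, the smallest 462 splits allow, adjusted p = 0.00487). B cells were 8.32% ± 1.80 against 19.8% ± 8.82 (exact permutation p = 0.0130, adjusted p = 0.0234), with overlap, and leaving out any 1 OF library ended this call (adjusted p up to 0.0686). Hepatocytes (0.379% and 2.67%), phagocytes (6.76% and 11.8%), dendritic cells (9.87% and 6.57%) and neutrophils (2.71% and 3.51%) did not pass (exact permutation p = 0.310, 0.251, 0.123 and 0.729). Over cells of at least 6624 UMIs, which leaves out most T and NK cells of OF (medians of 2425 to 4655), their difference was 2.63 points (exact permutation, adjusted p = 0.812). Against OC 1 and 3 alone, whose lowest counts are 745 and 500, it was 38.5 points.

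**Figure D1:**
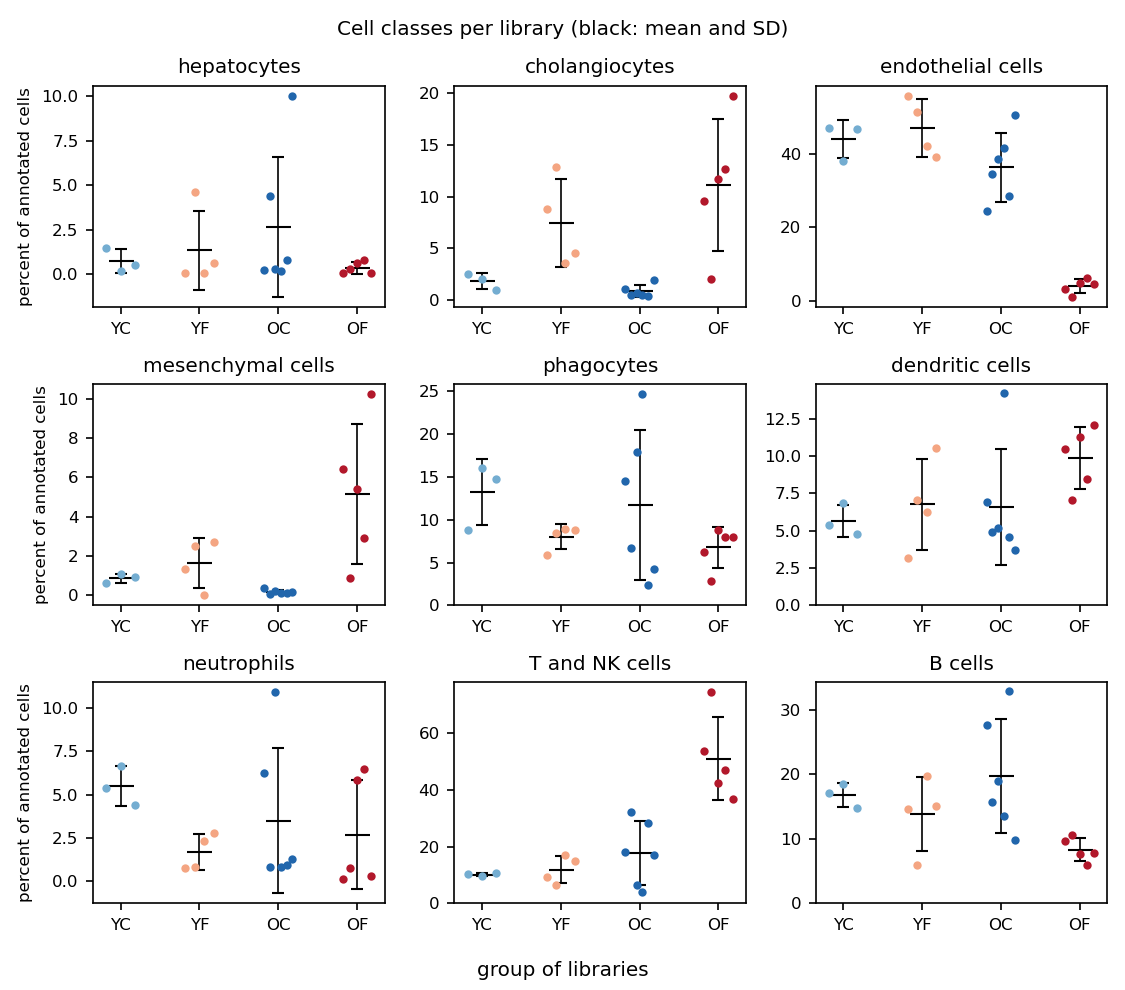
Percent of annotated cells per library in 9 cell classes for young control (YC), young enriched (YF), old control (OC) and old enriched (OF) libraries, with points for libraries and bars for the mean and SD. Endothelial cells were 3.97% in OF and 36.3% to 46.9% in the other groups, and T and NK cells were 51.0% in OF and 10.2% to 17.8% in the others.

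Summed over the endothelial class, genes of liver sinusoids were lower in OF than in OC. The groups hold different cells of this class, as by own clusters those of OF lay mostly in cluster 17 (led by Ednrb, Mmrn1 and Ly6c1) and those of OC in clusters 0 and 1. A change within 1 kind of endothelial cell was not tested. Stab2, a scavenger receptor of sinusoids, fell by 2.65 ± 0.24 (adjusted p = 4.24e-08), from 905.8 to 144.1 CPM. Mrc1 fell by 2.36 ± 0.23, Gpr182 fell by 2.38 ± 0.23, Plxnc1 fell by 2.47 ± 0.21 and the iron exporter Slc40a1 fell by 2.92 ± 0.26 (adjusted p at most 9.2e-08). Adam23 (ENSMUSG00000025964, chromosome 1, 63445891 to 63596276, GRCm38) fell by 3.12 ± 0.27 and Cntfr fell by 3.29 ± 0.53. Higher were the progenitor and vessel marker Cd34 (3.40 ± 0.42, adjusted p = 1.19e-05), the adhesion receptor Selp (3.67 ± 0.44), the fenestral diaphragm gene Plvap (1.68 ± 0.18) and Sox17 (1.16 ± 0.16). Among genes with an average log2 CPM of at least 5 and no overlap between libraries, the largest increases were in Emp1 (ENSMUSG00000030208, chromosome 6, 135362545 to 135383173), at 8.52 ± 0.75 (adjusted p = 5.28e-07), from 2.13 to 781.7 CPM, Igfbp3 at 7.71 ± 1.08 and the neuropeptide gene Nts at 7.53 ± 0.92. The less expressed cytokine Il6 rose with them, at 8.09 ± 0.66, and the cell cycle inhibitor Cdkn1a at 3.36 ± 0.32 (adjusted p at most 3.0e-07), and so did Icam1 (2.55 ± 0.19) and Nfkbiz (3.30 ± 0.35). In all 4869 of 13063 genes were called, 2668 higher and 2201 lower. Of all genes tested, 18.1% had no overlap in endothelial cells, 9.01% in phagocytes and 14.0% in T and NK cells (0.433% by chance), and 17.3% in cholangiocytes (3.57%).

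By list, 15 of 16 sinusoidal identity genes fell (15 adjusted over the list alone) with a median of -2.33 (camera adjusted p = 1.79e-09, and 0.161 with an estimated correlation). Of 15 capillarised vascular genes 11 rose by either count, with a median of 1.12 (1.41e-04, and 0.161 estimated). NF-kB inflammation genes rose in 11 of 16 (13 over the list alone, 1.89e-06, and 0.161 estimated). Senescence and secretory genes were 14 higher and 2 lower of 26 (16 and 3 over the list alone, 4.33e-05, and 0.143 estimated), and dissociation stress genes rose in 17 of 20 (18 over the list alone, 1.72e-13, and 0.161 estimated). Antigen presentation genes were higher in 3 of 8 by either count, among them H2-DMa (1.73) and Cd74 (1.68) (adjusted p = 0.0277, and 0.573 estimated). Pericentral genes went both ways, Rspo3 (1.65) and Thbd (1.66) higher, Kit (-1.81) and Wnt2 (-1.05) lower (0.389). Erythroid genes had a median of 2.45 with none called (0.0390, and 0.556 estimated). Interferon response (6 higher, 2 lower, 0.357), cell cycle (4 higher, 1 lower, 0.598), hepatocyte free RNA (0.158), Kupffer genes (0.268) and mitochondrial genes (1 lower, 0.317) were not called.

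**Figure D2:**
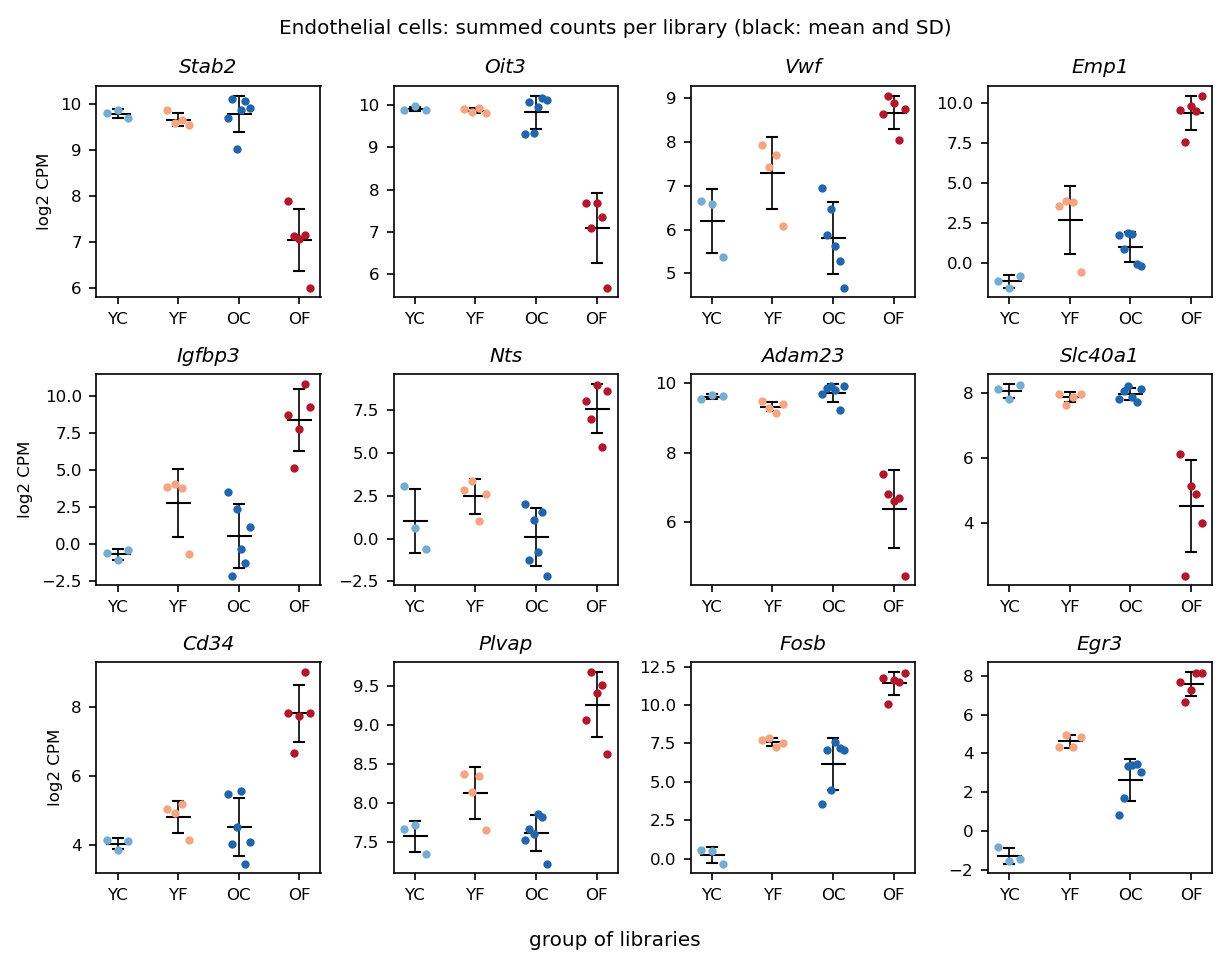
Endothelial log2 CPM of 12 genes per library in YC, YF, OC and OF, from counts summed over the class, with points for libraries and bars for the mean and SD. Stab2, Oit3, Adam23 and Slc40a1 were lowest in OF, and Vwf, Emp1, Igfbp3, Nts, Cd34, Plvap, Fosb and Egr3 were highest there.

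In cholangiocytes (n = 5 and 3) the cornified envelope gene Sprr1a (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895) had 6675 counts in OF and 1 in OC, a ratio of 300 (95% interval 53.8 to 11848). The AP-1 gene Fosl1 had a ratio of 89.5 (24.8 to 740) from 2 counts in OC. The urokinase receptor Plaur rose by 3.22 ± 0.41 (adjusted p = 1.44e-04), the tight junction gene Cldn4 by 3.46 ± 0.47 (3.04e-04) and Cdkn1a by 2.51 ± 0.59 (0.0182). Cldn7 rose by 0.53 ± 0.16 (0.0389), and Epcam was at 0.40 ± 0.17 (0.155). Endothelial Dnase1l3 fell by 7.61 ± 0.86, Ptprb fell by 7.10 ± 0.62 and Kdr fell by 6.29 ± 0.75. The endothelial list was at 0.0760% of cholangiocyte UMIs in OC and 0.00322% in OF. Whether this is RNA of endothelial cells, far fewer in OF, was not tested. Of 11696 genes 1171 were called, 732 higher (62.5%, and 45.6% without TMM) and 439 lower. With a dissociation share covariate, chosen after the data were seen, 84 genes were called, and 2797, 2230 and 2695 in endothelial cells, phagocytes and T and NK cells. Ductular reaction genes rose in 3 of 14 by either count, Ncam1 the third with a ratio of 6.58 (1.81 to 54.6) from 2 counts in OC (adjusted p = 0.0242, and 0.161 with an estimated correlation). Senescence and secretory genes were 5 higher and 1 lower of 17 (6 and 1 over the list alone, 6.02e-04, and 0.143 estimated), and dissociation stress genes rose in 7 of 20 (14 over the list alone, 3.29e-08, and 0.317 estimated). Erythroid genes were higher in 1 of 5, Hbb-bs (4 over the list alone, 0.00115, and 0.317 estimated), hepatocyte free RNA was lower with none called (median -1.18, 7.01e-04, and 0.458 estimated), and so were mitochondrial genes (-0.45, 0.0166, and 0.573 estimated). Cell cycle was not called (3 higher, 0.181), with a median of -0.05 below and a test above 0.

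In phagocytes of OF (n = 5 and 6) several genes of Kupffer cells were lower. By own clusters OF phagocytes lay mostly in cluster 2, with few in the Kupffer cluster 10, and those of OC in both. Slc40a1 fell by 3.17 ± 0.52 (adjusted p = 4.41e-04), the scavenger receptor Marco fell by 5.37 ± 1.31 (0.00982) and Timd4 fell by 3.34 ± 0.86 (0.0129), each with overlap between libraries. The lipid droplet gene Plin2 rose by 1.21 ± 0.13 (2.53e-06), Trem2 by 0.93 ± 0.24 (0.00964) and Cd9 by 1.08 ± 0.30 (0.0165), and Spp1 was at 2.59 ± 0.88 (0.0522). Vegfa rose by 3.22 ± 0.29 (3.74e-07), Cd74 by 1.24 ± 0.27 (0.00260), H2-Ab1 by 1.20 ± 0.37 (0.0286) and Cxcl2 by 2.06 ± 0.56 (0.0163). Interferon-induced Rtp4 fell by 1.20 ± 0.22 (5.56e-04), Ifit3 fell by 1.76 ± 0.42 (0.00675) and Xaf1 fell by 1.05 ± 0.22 (0.00235). Endothelial transcripts were also lower, as Clec4g fell by 4.78 ± 0.69 (1.1e-04), Ptprb fell by 4.89 ± 0.89 and Aqp1 fell by 3.13 ± 0.63, and globin genes were higher, as Hbb-bs at 6.06 ± 1.32 (0.00485). Of 10909 genes 2157 were called, 1253 higher (58.1%, and 38.2% without TMM) and 904 lower. With a hepatocyte free RNA covariate 1040 genes were called.

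By list in phagocytes, Kupffer identity fell in 7 of 16 (10 over the list alone, median -2.38, camera adjusted p = 0.0168, and 0.679 with an estimated correlation). Scar-associated macrophage genes rose in 3 of 14 (7 over the list alone, 3.89e-04, and 0.317 estimated), antigen presentation in 4 of 8 (6 over the list alone, 0.00219, and 0.458 estimated), and senescence and secretory genes were 9 higher and 1 lower of 23 (11 and 1, 2.85e-04, and 0.304 estimated). Interferon response genes fell in 8 of 19 (11 over the list alone, median -0.98, 4.66e-05, and 0.351 estimated). Monocyte identity was lower with none called (median -0.35, 0.0224, and 0.540 estimated). Endothelial genes fell in 7 of 8 by either count (median -3.19, 1.89e-06, and 0.161 estimated), hepatocyte free RNA in 3 of 22 (2 over the list alone, 3.11e-05, and 0.458 estimated), and erythroid genes rose in 4 of 4 by either count (median 5.68, 4.66e-05, and 0.170 estimated). NF-kB inflammation (3 higher, 0.128), dissociation stress (4 higher, 0.184), cell cycle (2 higher, 0.252), mitochondrial (1 lower, 0.0518) and lymphocyte genes (0.948, median 0.17 above and test below 0) were not called.

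T and NK cells of OF (n = 5 and 6) rose in Cdkn1a by 3.88 ± 0.34 (adjusted p = 2.57e-07), from 20.2 to 334.8 CPM, and in Vegfa by 3.18 ± 0.49 (1.2e-04). The checkpoint receptor Ctla4 rose by 1.34 ± 0.29 (0.00202) and Nr4a1 by 1.83 ± 0.38 (0.00168). Proliferation genes Pcna (1.09 ± 0.15) and Stmn1 (1.35 ± 0.25) and the naive T cell factor Satb1 (0.99 ± 0.23) were higher. Mitd1 fell by 1.99 ± 0.18, Fam78a fell by 1.98 ± 0.20 and Zfp512 fell by 1.57 ± 0.20. Of 11297 genes 3573 were called, 1976 higher (55.3%, and 37.7% without TMM) and 1597 lower. Dissociation stress rose in 9 of 20 (10 over the list alone, 0.00115, and 0.556 with an estimated correlation), senescence and secretory genes were 7 higher and 1 lower of 19 by either count (0.0242, and 0.317 estimated), and cell cycle rose in 4 of 13 by either count (0.0330, and 0.351 estimated). Erythroid genes rose in 5 of 5 by either count (4.77e-04, and 0.317 estimated), at 0.490% ± 0.253 of UMIs against 0.0152% ± 0.0326. Effector and exhaustion (1 higher, 0.905, median -0.06 below and test above 0), naive (2 higher, 1 lower, 0.608), interferon response (1 higher, 4 lower, 0.167), hepatocyte free RNA (1 lower, 0.126) and mitochondrial genes (0.357) were not called. By own clusters, T and NK cells of OF lay mostly in clusters 6, 8, 11, 14 and 18 and those of OC in cluster 3. Cluster 18, T cells by the authors' names, was led by globin genes, Tnfrsf4 and Ctla4 and named erythroid here.

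YF was compared with YC to ask the same of young mice (n = 4 and 3). Immediate early and heat shock genes were far higher in YF in every class tested. Fosb rose by 7.68 ± 1.03 in endothelial cells (adjusted p = 5.67e-04), 7.32 ± 0.86 in T and NK cells (2.25e-05), 7.16 ± 0.77 in cholangiocytes (7.38e-04), 6.47 ± 0.40 in phagocytes (1.6e-09) and 6.09 ± 0.51 in mesenchymal cells (1.27e-05). In phagocytes the neutrophil attractant Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938) rose by 6.80 ± 0.95 (2.58e-04), Ccl4 by 5.64 ± 0.74 (1.37e-04) and Cdkn1a by 3.39 ± 0.31 (6.21e-07). All YC libraries and only YF 1b carry the set 2 label with its diet protocol, so label set is nearly tied to this comparison. With YF 1b as the only YF library, taken to vary like the libraries of the other groups, cholangiocytes, phagocytes and T and NK cells gave 212, 167 and 349 called genes against 127, 591 and 1195. With the dissociation share covariate edgeR called 7, 12 and 83 genes in these classes and 147 in endothelial cells. It called 0 in mesenchymal cells (885 at an unadjusted p under 0.05), where DESeq2 without the covariate called 187. The share never overlaps between YF and YC, so lost calls show no cause. Over all genes tested, 14.1% to 30.4% had no overlap between YF and YC (5.71% by chance), and 16.1% in mesenchymal cells (10%).

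Shares in YF and YC passed no adjusted test. Cholangiocytes were 7.47% ± 4.26 against 1.87% ± 0.771 (exact permutation p = 0.0857), and neutrophils 1.69% ± 1.03 against 5.49% ± 1.15 (exact permutation p = 0.0286, the smallest 35 splits allow, adjusted p = 0.257). The phagocyte difference was -5.21 points from the 13.2% of YC (exact permutation p = 0.0571, adjusted p = 0.257). Means were endothelial cells 46.9% and 43.9%, T and NK cells 11.9% and 10.2%, B cells 13.8% and 16.8%, mesenchymal cells 1.65% and 0.882%, dendritic cells 6.75% and 5.65%, and hepatocytes 1.35% and 0.730%.

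In endothelial cells Egr3 rose by 6.80 ± 0.65 (3.82e-05), Junb by 3.88 ± 0.39 (3.23e-05), Nfkbiz by 3.59 ± 0.49 (4.51e-04), Ier3 by 3.40 ± 0.41 and Icam1 by 1.83 ± 0.25 (1.95e-04). Rgs16 had a ratio of 447 (95% interval 80.0 to 17698), from 1 count in YC. Leng8 fell by 1.08 ± 0.22, Ccnt2 fell by 0.74 ± 0.18 and Herc4 fell by 0.63 ± 0.16. Called were 313 genes, 296 higher (94.6%, and 76.0% with DESeq2) and 17 lower, with 145 called without YC 3 and 721 with DESeq2. Endothelial cells of YF 1b lay mostly in cluster 6 and those of YC in clusters 1, 2, 3 and 8. In cholangiocytes Atf3 rose by 6.11 ± 0.84 (0.00505), Nr4a1 by 5.31 ± 0.97 (0.0246) and Icam1 by 3.43 ± 0.71 (0.0447), and the only lower gene named was Clec2d, which fell by 0.92 ± 0.18 (0.0118). Called were 127 genes, 118 higher (92.9%, and 81.8% without TMM) and 9 lower, with 25 called without YC 1 and 228 with DESeq2. In T and NK cells Fos rose by 6.30 ± 0.93 (2.86e-04), Nr4a2 by 6.12 ± 0.63 (3.66e-06), Cdkn1a by 4.93 ± 0.52 (4.24e-06), Vegfa by 3.68 ± 0.67, Ctla4 by 2.58 ± 0.42 (4.93e-04), Ccl3 by 3.24 ± 0.90 (0.0317), Ccl4 by 2.59 ± 0.58 (0.00713) and Ifng by 2.20 ± 0.59 (0.0247). The NK receptor gene Klrd1 fell by 1.28 ± 0.29 (0.00565) and Dmac1 fell by 1.29 ± 0.24. Called were 1195 genes, 867 higher (72.6%, and 41.2% without TMM) and 328 lower, with 584 called without YC 3. T and NK cells of YF 1b lay mostly in cluster 13 and those of YC in clusters 9, 12 and 14.

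In phagocytes of YF, Ier3 rose by 4.24 ± 0.23 (2.46e-10), Cxcl1 by 6.70 ± 1.74 (0.0334), Ccl3 by 4.94 ± 0.76 (6.31e-04), Gpnmb by 5.82 ± 1.61 (0.0476), Plin2 by 0.72 ± 0.17 (0.0105), Top2a by 2.18 ± 0.57 (0.0276) and Pcna by 0.84 ± 0.20 (0.0112). Ogt fell by 1.10 ± 0.20, Ccnt2 fell by 1.04 ± 0.23 and Madd fell by 1.03 ± 0.21. Called were 591 genes, 539 higher and 52 lower, with 328 called without YC 3. In mesenchymal cells (n = 3 and 3) Egr1 rose by 3.97 ± 0.33 (1.27e-05), Atf3 by 4.50 ± 0.38 and Icam1 by 3.60 ± 0.37 (7.16e-05). Cxcl1 had a ratio of 99.4 (27.4 to 823) and Gdf15 of 44.3 (7.79 to 1766), from 2 and 1 counts in YC, and Fam71a and Lsmem1, at 0 counts in YC, were at least 17.7-fold and 8.78-fold higher. Cd200 fell by 1.73 ± 0.30, Hjurp fell by 1.54 ± 0.32 and Cav1 fell by 1.52 ± 0.34. The matrix gene Bgn (1.11 ± 0.33, 0.190) and Spp1 (3.97 ± 1.34, 0.302) were not called. Called were 123 genes, 114 higher and 9 lower. This count was 62 without YC 2 and 790 without YF 1b, the lowest and highest with 1 library left out.

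**Figure D3:**
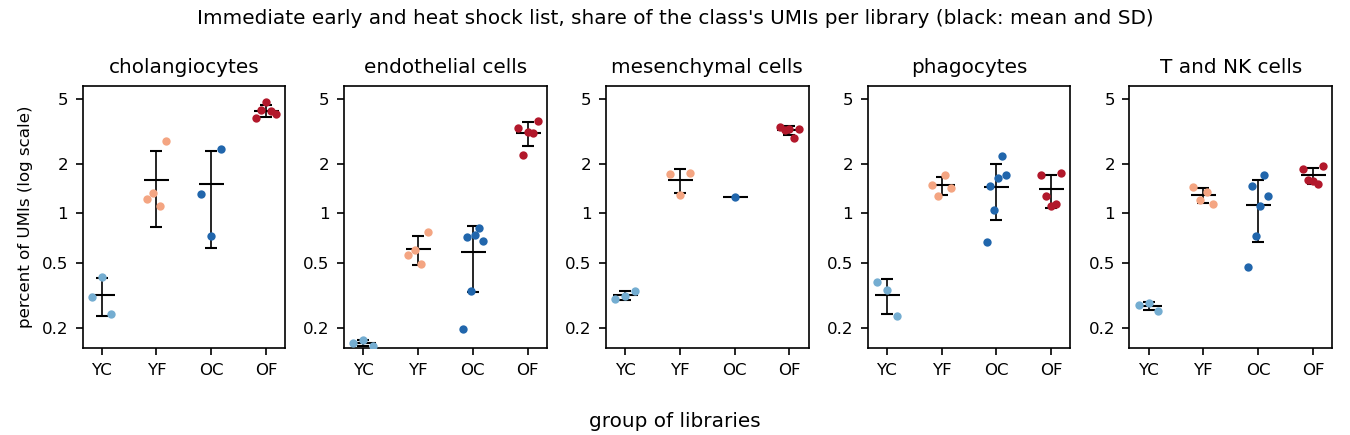
Share of the dissociation stress list (immediate early and heat shock genes) in the UMIs of 5 classes per library, on a log axis, with points for libraries and bars for the mean and SD. YC was lowest in each class (0.162% to 0.320%), and OF was at 4.22% in cholangiocytes, 3.10% in endothelial cells and 3.21% in mesenchymal cells.

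Of 20 dissociation stress genes 13 rose in cholangiocytes, 15 in endothelial cells, 16 in mesenchymal cells, 18 in phagocytes and 17 in T and NK cells (18, 17, 18, 18 and 19 adjusted over the list alone). All 5 of these tests held with an estimated correlation (adjusted p = 0.0110, 0.00280, 0.00280, 0.00387 and 0.0211). Senescence and secretory genes rose in 1 of 17 cholangiocyte, 6 of 26 endothelial, 7 of 24 mesenchymal, 12 of 23 phagocyte and 7 of 19 T and NK cell genes (6, 10, 9, 17 and 9 over the list alone). The call held in all but T and NK cells (0.00309, 0.00280, 0.00280, 0.00280 and 0.0646 estimated). NF-kB inflammation rose in 6 of 16 endothelial and 9 of 16 phagocyte genes (9 and 13 over the list alone, 0.0192 and 0.0401 estimated). Lists called only at the preset correlation were, in phagocytes, scar-associated macrophage (2 higher, 7 over the list alone, 0.00147, and 0.427 estimated), antigen presentation (none, 3 over the list alone, 1.71e-04, and 0.394 estimated), and cell cycle (3, 5 over the list alone, 2.14e-04, and 0.350 estimated). Others were endothelial genes (0.0274, and 0.562 estimated), lower hepatocyte free RNA (6.5e-04, and 0.615 estimated) and lower lymphocyte genes (0.00275, and 0.350 estimated). In mesenchymal cells they were fibrillar matrix (none called, 0.0316, and 0.776 estimated), stellate activation (1 higher, 1.71e-04, and 0.283 estimated), erythroid (none, 4 over the list alone, 9.55e-04, and 0.348 estimated) and endothelial genes (0.0198, and 0.615 estimated, median 0.23 above and test below 0). In T and NK cells they were effector and exhaustion (4 higher by either count, 0.0223, and 0.615 estimated), erythroid (1, 5 over the list alone, 0.0223, and 0.562 estimated) and mitochondrial (1 by either count, 0.0148, and 0.648 estimated). In endothelial cells they were antigen presentation (none called, 0.0460, and 0.674 estimated), lower hepatocyte free RNA (4.71e-06, and 0.462 estimated) and lower erythroid genes (0.0414, and 0.615 estimated), and in cholangiocytes erythroid genes (none, 4 over the list alone, 4.29e-05, and 0.210 estimated). Not called, with none called over all genes, were sinusoidal identity (0.1495), capillarised vascular (0.129), pericentral (0.709, median 0.01 above and test below 0), Kupffer identity (0.306), monocyte identity (0.838), ductular reaction (0.725), naive (0.787), stellate quiescence (0.480), portal fibroblast (0.725) and interferon response (0.265 to 0.852). Nor were cell cycle outside phagocytes (2 higher in T and NK cells, 0.265 to 0.767), mitochondrial genes outside T and NK cells (0.1492 to 0.8383), hepatocyte free RNA in cholangiocytes, mesenchymal cells and T and NK cells (0.220 to 0.670), Kupffer genes in endothelial cells (0.810) and erythroid genes in phagocytes (0.965).

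OF was compared with YF to ask how the enriched niche differs with age (n = 5 and 4). Endothelial cells were 3.97% ± 1.97 in OF and 46.9% ± 7.75 in YF, and T and NK cells 51.0% ± 14.6 and 11.9% ± 4.84, without overlap (exact permutation p = 0.00794 each, the smallest 126 splits allow, adjusted p = 0.0357). Over cells of at least 6624 UMIs, with most T and NK cells of OF left out, the differences were -49.0 and 5.03 points (adjusted p = 0.0714 and 0.902). Within label set 1 they were -45.6 and 40.1 points (exact permutation p = 0.0179 each, the smallest 56 splits allow, adjusted p = 0.0804). Cholangiocytes (11.1% and 7.47%), mesenchymal cells (5.17% and 1.65%), B cells (8.32% and 13.8%), dendritic cells (9.87% and 6.75%), phagocytes, neutrophils and hepatocytes did not pass (exact permutation p = 0.0794 to 0.508). By own clusters endothelial cells of YF 1 to 3 lay mostly in clusters 1 and 13 and those of OF in cluster 17, and changes are of the class as a whole. Stab2 in endothelial cells fell by 2.49 ± 0.25 (adjusted p = 3.16e-07), Oit3 fell by 2.59 ± 0.26, Mrc1 fell by 2.47 ± 0.24 and Kit fell by 2.27 ± 0.26, while Cd34 rose by 3.24 ± 0.48 and Vcam1 by 1.42 ± 0.21. Emp1 rose by 6.31 ± 0.77 (1.89e-05), Gdf15 by 6.02 ± 0.83, Igfbp3 by 5.85 ± 1.12, Il6 by 7.90 ± 0.71 (5.68e-07), Tnfaip3 by 2.64 ± 0.21 and Plaur by 3.18 ± 0.27. The prostaglandin-degrading Hpgd fell by 3.81 ± 0.35, Ackr4 fell by 3.02 ± 0.57, Plet1os fell by 2.98 ± 0.33 and the Wnt ligand Wnt2 fell by 1.58 ± 0.26. Called were 4779 of 13063 genes, 2520 higher and 2259 lower.

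Mesenchymal cells of OF (n = 5 and 3) were lower in quiescent stellate cell genes. Changes are of the class as a whole. Own cluster 33 (led by Acta2) held 349 of 1198 OF cells and 29 of 209 of YF 1 to 3. The retinol esterifying Lrat fell by 4.85 ± 0.34 (adjusted p = 2.07e-06), from 398.9 to 11.7 CPM, Vipr1 fell by 5.46 ± 0.42 (7.04e-06), Angptl6 fell by 5.78 ± 0.49 and Gdf2 fell by 4.91 ± 0.38 (5.54e-06). Fcna fell by 8.66 ± 0.62 from 1683 counts in YF to 4 in OF. The sinusoidal endothelial gene Clec4g and Colec10 were lower by ratios of 585 (200 to 2841) and 347 (118 to 1687) from 3 counts each in OF. Il6 rose by 4.52 ± 0.40 (1.41e-05), the aggrecanase Adamts4 by 3.63 ± 0.47 (6.22e-04), Tnfrsf12a by 2.99 ± 0.60 (0.0165), Ccn2 by 1.87 ± 0.41 (0.0185), Cdkn1a by 1.91 ± 0.47 (0.0356) and Cxcl1 by 2.10 ± 0.51 (0.0338). Matrix genes Lum (0.55 ± 0.28, 0.271) and Lox (1.41 ± 0.51, 0.130) were not called. Called were 614 of 11142 genes, 336 higher and 278 lower, and 97 with a hepatocyte free RNA covariate and 30 with the dissociation share covariate. Stellate quiescence fell in 12 of 15 genes (13 over the list alone, median -2.83, 2.49e-21), and this held with an estimated correlation (0.0408). Endothelial genes (median -6.92) and hepatocyte free RNA (-2.55) fell too, called at the preset correlation only. Stellate activation rose in 1 of 15 (2 over the list alone, 3.36e-05, and 0.248 estimated), and fibrillar matrix (0.187) and portal fibroblast genes (0.806) had none called. With the replicate number as a block both lists were lower and called (0.0089 and 0.024), and within label set 1 both were lower and not called (0.342).

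In cholangiocytes of OF Sprr1a rose by 5.80 ± 0.44 (2.76e-06), Fosl1 by 5.43 ± 0.42 (7.79e-06), Plaur by 3.44 ± 0.30 (3.19e-06), Cldn4 by 2.36 ± 0.32 (1.63e-04), Ncam1 by 1.35 ± 0.39 (0.0167), Cdkn1a by 2.48 ± 0.48 (0.00360) and Ccl5 by 2.86 ± 0.87 (0.0344). Endothelial Dnase1l3 fell by 6.53 ± 0.77 and Ptprb fell by 5.71 ± 0.57 (list 0.0279% of UMIs in YF, 0.00322% in OF). The hepatocyte gene Mup3 fell by 5.99 ± 1.03. Called were 2835 genes, 1503 higher and 1332 lower. In phagocytes Gpnmb rose by 4.30 ± 0.99 (0.00608), Mmp19 by 3.71 ± 0.37 (3.93e-06), Vegfa by 3.67 ± 0.33 (1.51e-06), Lgals3 by 1.18 ± 0.27 (0.00335), Trem2 by 1.23 ± 0.27 (0.00288) and Plin2 by 1.11 ± 0.15 (3.99e-05). Timd4 fell by 5.11 ± 0.87 (7.75e-04), Fcna fell by 4.83 ± 1.02 (0.00364), and Slc40a1 fell by 3.39 ± 0.55. Ifit3 fell by 2.00 ± 0.43, Rtp4 fell by 1.41 ± 0.23, Cdk1 fell by 1.87 ± 0.49, Aqp1 fell by 5.71 ± 0.60, Clec4g fell by 6.68 ± 0.64 and Ptprb fell by 6.82 ± 0.88. Called were 2435 genes, 1252 higher (51.4%, and 38.0% without TMM) and 1183 lower, and 452 with the free RNA covariate. By own clusters T and NK cells of YF 1 to 3 lay mostly in clusters 3 and 11, with few in clusters 6, 8 and 14 that hold most of OF, and phagocytes of YF 1 to 3 mostly in cluster 10 and of OF in cluster 2. In T and NK cells Gzmk (ENSMUSG00000042385, chromosome 13, 113171608 to 113225908) rose by 2.82 ± 0.65 (0.00958), Pdcd1 by 2.67 ± 0.67 (0.0145), Ctla4 by 1.45 ± 0.33 (0.00700), Ramp3 by 2.97 ± 0.61 (0.00500) and Pxdc1 by 2.52 ± 0.67 (0.0187). Perforin, Prf1, fell by 1.15 ± 0.29 (0.0125) and Lef1 fell by 0.70 ± 0.24 (0.0489). Scd1 fell by 4.77 ± 1.24, hepatocyte Mup3 fell by 4.37 ± 0.93 and endothelial Ptprb fell by 4.14 ± 0.75. YF 2 held the most hepatocyte RNA here, 0.341%. Called were 1849 genes, 1107 higher and 742 lower. Without YF 1b there were 1172, and 385 in mesenchymal cells. Over all genes tested, 14.7% to 24.2% had no overlap between OF and YF (1.59% by chance), and 12.6% in mesenchymal cells (3.57%). With the dissociation share covariate 290 genes were called in cholangiocytes, 3050 in endothelial cells, 2502 in phagocytes and 1642 in T and NK cells.

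Among the other lists in OF against YF, senescence and secretory genes in endothelial cells were 18 higher and 2 lower of 26 (19 and 3 over the list alone) and held with an estimated correlation (0.0495), as did endothelial genes in phagocytes, lower in 7 of 8 (8 over the list alone, 0.0495). Called only at the preset correlation in endothelial cells were sinusoidal identity (15 of 16 lower by either count, 7.39e-10, and 0.153 estimated), capillarised vascular (10 of 15 higher by either count, 6.79e-05, and 0.127 estimated), and NF-kB inflammation (15 of 16 higher by either count, 4.17e-09, and 0.0558 estimated). They were joined by antigen presentation (4 of 8 higher, 5 over the list alone, 0.00554, and 0.575 estimated) and dissociation stress (17 of 20 higher, 19 over the list alone, 7.78e-14, and 0.139 estimated). In phagocytes they were Kupffer identity (11 of 16 lower, 13 over the list alone, 8.69e-06, and 0.537 estimated), scar-associated macrophage (7 of 14 higher by either count, 0.00103, and 0.469 estimated), and interferon response (8 of 19 lower, 12 over the list alone, 1.05e-05, and 0.424 estimated). Further ones were cell cycle (5 of 18 lower by either count, 0.00880, and 0.575 estimated), NF-kB inflammation (4 of 16 higher, 5 over the list alone, 0.0114, and 0.602 estimated), and antigen presentation (none called, 0.0291, and 0.602 estimated). Lists of RNA quality and other cells were hepatocyte free RNA (14 of 22 lower, 19 over the list alone, 1.48e-06, and 0.488 estimated), mitochondrial (5 of 10 lower by either count, 0.00451, and 0.597 estimated) and erythroid genes (none called, 0.0196, and 0.551 estimated). In mesenchymal cells they were senescence and secretory (4 higher and 1 lower of 24, 7 and 1 over the list alone, 6.79e-05, and 0.0558 estimated) and dissociation stress (8 of 20 higher, 10 over the list alone, 4.17e-09, and 0.127 estimated). Lower in mesenchymal cells were hepatocyte free RNA (11 of 22 lower, 17 over the list alone, 5.1e-10, and 0.301 estimated) and endothelial genes (6 of 8 lower, 8 over the list alone, 2.52e-09, and 0.163 estimated). In cholangiocytes they were senescence and secretory (6 of 17 higher, 7 higher and 1 lower over the list alone, 0.00522, and 0.127 estimated) and dissociation stress (13 of 20 higher, 16 over the list alone, 2.52e-09, and 0.314 estimated). There were also hepatocyte free RNA (8 of 22 lower by either count, 0.00417, and 0.583 estimated) and mitochondrial genes (2 of 10 lower, 4 over the list alone, 0.0266, and 0.628 estimated). In T and NK cells they were hepatocyte free RNA (5 of 22 lower, 13 over the list alone, 2.6e-05, and 0.575 estimated) and mitochondrial genes (5 of 10 lower by either count, 6.26e-04, and 0.569 estimated). Effector and exhaustion (4 higher, 1 lower, 0.191), naive (2 lower, 0.412), monocyte identity (0.383), pericentral (1 higher, 2 lower, 0.566), ductular reaction (2 higher, 0.302) and Kupffer genes in endothelial cells (0.217) were not called. Nor were dissociation stress (2 higher each, 0.6575 and 0.1871) and senescence and secretory genes (3 and 1 higher, 1 lower each, 0.1374 and 0.4665) in phagocytes and T and NK cells, or interferon response in endothelial (4 higher, 2 lower, 0.6575) and T and NK cells (1 higher, 2 lower, 0.09746). Nor were cell cycle (4 higher, 2 lower in endothelial cells, 1 each in cholangiocytes, 0.8036 to 0.9771) and erythroid genes (0.0511 to 0.1265) outside phagocytes, hepatocyte free RNA (2 lower, 0.09746) and mitochondrial genes in endothelial cells (5 lower, 0.09439), mitochondrial genes in mesenchymal cells (0.4231) and lymphocyte genes (1 lower, 0.849).

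OC was compared with YC to ask how the whole liver differs with age (n = 6 and 3). OC is all of label set 1 and YC of set 2, so age and label set cannot be told apart here. The own cluster led by Gzma in each set held 522 of 4081 OC cells and 551 of 2167 YC cells in T and NK clusters. Changes are of the whole class, so a different mix is not excluded. In T and NK cells of OC Gzmk rose by 3.49 ± 0.75 (adjusted p = 0.0122), Tox by 1.96 ± 0.45 (0.0155) and Ctla4 by 2.69 ± 0.41 (7.89e-04), and Gzma fell by 1.95 ± 0.43 (0.0112). Plac8 fell by 1.64 ± 0.43 (0.0296), Ifitm2 fell by 1.56 ± 0.35, Stmn1 fell by 1.52 ± 0.28 and Lef1 fell by 0.83 ± 0.25 (0.0446). Fosb rose by 6.75 ± 0.83 (1.65e-04), Fos by 6.24 ± 0.91 and Atf3 by 5.50 ± 1.10. Called were 826 of 11297 genes, 543 higher and 283 lower, and 514 with the free RNA covariate and 235 without YC 3. With the dissociation share covariate 11 genes were called in T and NK cells, 24 in phagocytes, 92 in endothelial cells and 9 in cholangiocytes. No share passed its test. Mesenchymal cells were 0.175% ± 0.101 against 0.882% ± 0.229 (exact permutation p = 0.0119, the smallest 84 splits allow, adjusted p = 0.107), and cholangiocytes 0.877% ± 0.598 against 1.87% ± 0.771 (exact permutation p = 0.0595). Means were endothelial cells 36.3% and 43.9%, T and NK cells 17.8% and 10.2%, B cells 19.8% and 16.8%, and phagocytes 11.8% and 13.2%.

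In phagocytes of OC the scavenger receptor gene Cd163 fell by 2.82 ± 0.70 (0.0205) and Timd4 fell by 2.41 ± 0.67 (0.0355), the 1 of 16 Kupffer identity genes called. Higher were Gpnmb (8.59 ± 1.58, 0.00396), Cd63 (4.37 ± 1.03, 0.0160), Trem2 (1.23 ± 0.29, 0.0127), Itgam (1.03 ± 0.27, 0.0191) and Ccr2 (1.08 ± 0.34, 0.0494). Gdf15 rose by 6.39 ± 1.04 (0.00160), Cxcl2 by 6.07 ± 0.91 (7.82e-04), Fosb by 5.35 ± 0.37 (2.02e-08), Cdkn1a by 2.96 ± 0.30 and Vegfa by 3.24 ± 0.42. Serpina1e fell by 3.18 ± 0.75 and Hbb-bt fell by 5.25 ± 1.57 (erythroid 0.137% in YC 1, at most 0.00699% in YC 2 and 3). Called were 1082 of 10909 genes, 671 higher (62.0%, and 50.7% without TMM) and 411 lower. This became 100 with the free RNA covariate and 275 without YC 3. In endothelial cells the LIM homeobox gene Lhx6 fell by 1.43 ± 0.33 (0.0250), Ccdc152 fell by 2.16 ± 0.34 (0.00289), Serpina1e fell by 2.89 ± 0.67 (0.0317) and Kit fell by 0.90 ± 0.24 (0.0420). Vcam1 rose by 1.20 ± 0.22 (0.00344), Nfkbiz by 3.76 ± 0.48, Ccl3 by 3.66 ± 0.56, Fosb by 6.80 ± 0.98, Fos by 5.63 ± 0.75 and Egr3 by 5.07 ± 0.67. Wnt9b (-1.64 ± 0.52, 0.123) and Rspo3 (-1.15 ± 0.46, 0.231) were not called. Called were 359 genes, 270 higher and 89 lower. This count was 100 without YC 1, 554 without OC 3, 906 with DESeq2 and 37 with the replicate block. Cholangiocytes (n = 3 and 3) rose in Fosb by 6.55 ± 0.77 (0.00437), Atf3 by 5.68 ± 0.85 (0.0117) and Fos by 5.23 ± 1.06 (0.0393), and Tgfb2 fell by 1.57 ± 0.30 (0.0187), the sterol synthesis gene Mvd fell by 1.53 ± 0.37 (0.0475) and Igf1 fell by 1.45 ± 0.26 (0.0109). Called were 179 genes, 88 higher (49.2%, and 37.0% without TMM) and 91 lower, and 13 called without YC 1 and 467 with DESeq2. Over all genes tested, 9.51% to 15.3% had no overlap between OC and YC (2.38% by chance), and 20.1% in cholangiocytes (10%).

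Dissociation stress rose in OC in 11 of 20 genes in cholangiocytes, 15 in endothelial cells, 17 in phagocytes and 16 in T and NK cells (16, 19, 19 and 20 over the list alone), with adjusted p = 0.0958, 0.00449, 0.0194 and 0.0399 with an estimated correlation. NF-kB inflammation rose in 9 of 16 endothelial and 13 of 16 phagocyte genes (12 and 15 over the list alone, 0.00449 and 0.0442 estimated). Senescence and secretory genes rose in 7 of 26 endothelial and 12 of 23 phagocyte genes (12 over the list alone, and 13 higher and 1 lower, 0.00278 and 0.0442 estimated). At the preset correlation alone they rose in cholangiocytes (none, 7 over the list alone, 0.0125, and 0.140 estimated) and T and NK cells (5 higher and 1 lower, 6 and 1 over the list alone, 0.0243, and 0.359 estimated). Also called only at the preset correlation were effector and exhaustion in T and NK cells (6 of 16 higher, 9 higher and 1 lower over the list alone, 1.15e-04, and 0.359 estimated). In phagocytes this held for Kupffer identity (1 of 16 lower by either count, median -1.26, 2.73e-04, and 0.496 estimated) and monocyte identity (2 of 12 higher, 7 over the list alone, 2.1e-04, and 0.350 estimated). It also held for scar-associated macrophage (6 of 14 higher, 7 over the list alone, 0.00701, and 0.438 estimated) and antigen presentation (none, 0.0120, and 0.503 estimated). Lists of other cells called there were hepatocyte free RNA (3 lower, 1 higher and 6 lower over the list alone, 7.28e-05, and 0.449 estimated) and erythroid (1 of 4 lower, 4 over the list alone, 0.00520, and 0.359 estimated). Lymphocyte (2 of 9 lower by either count, 0.0206, and 0.436 estimated) and endothelial genes (1 of 8 lower by either count, 0.00419, and 0.359 estimated) were lower too. In endothelial cells they were pericentral genes (1 of 6 lower, 4 over the list alone, median -0.81, 1.1e-05, and 0.0594 estimated) and antigen presentation (none, 2 over the list alone, 3.7e-04, and 0.359 estimated). Also there were hepatocyte free RNA (1 of 22 lower, 2 over the list alone, 2.46e-07, and 0.359 estimated) and lower erythroid genes (none, 0.00785, and 0.421 estimated), and T and NK cells had lower hepatocyte free RNA (none, 1.15e-04, and 0.503 estimated). Sinusoidal identity (0.407), capillarised vascular (1 higher, 0.392), Kupffer genes in endothelial cells (0.595, median 0.94 above and test below 0), ductular reaction (0.191), naive (2 lower, 0.261), interferon response (0.109 to 0.357), cell cycle (1 lower each in phagocytes and T and NK cells, 0.167 to 0.652) and mitochondrial genes (0.167 to 0.652) were not called, nor were hepatocyte free RNA (0.883) and erythroid genes (0.789) in cholangiocytes and erythroid genes in T and NK cells (0.6415).

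The difference between the old and the young effect of enrichment was tested for 46 gene and class pairs named in either comparison, and 29 differed (edgeR, adjusted p under 0.05, 20 to 32 under the alternatives). These pairs were picked for a large change in at least 1 of the 2 comparisons, which favours a difference. Over all genes 91 of 11297 differed in T and NK cells, 164 of 11696 in cholangiocytes, 225 of 10909 in phagocytes and 2308 of 13063 in endothelial cells. Label set is tied to this test through YC. The change in old minus that in young was -2.83 ± 0.40 for Adam23 (adjusted p = 7.63e-06) and -2.72 ± 0.36 for Slc40a1 (4.83e-06) in endothelial cells, and 6.61 ± 1.35 for Nts (5.51e-04). In cholangiocytes it was 6.99 ± 2.22 for Sprr1a (0.0154) and -6.76 ± 0.80 for endothelial Ptprb (2.12e-05). In phagocytes it was -5.94 ± 0.84 for Clec4g (2.04e-05), from -4.78 in old mice and 1.16 in young ones, the latter not called (0.168). Cxcl2 rose by 2.06 and 6.80, a difference of -4.75 ± 0.98 (5.16e-04). In T and NK cells it was -7.03 ± 1.05 for Fos (3.98e-05), from -0.72 in old mice, not called (0.335), and 6.30 in young ones. Nr4a2 rose by 1.67 and 6.12, a difference of -4.45 ± 0.67 (3.14e-05). No difference was called for Igfbp3 in endothelial cells (3.11 ± 2.24, 0.252) or for Hbb-bs in T and NK cells (-0.22 ± 2.04, 0.929). Emp1 depends on naming, since the endothelial class of YC and YF 1b lacks a cluster of vessel cells (27) like one kept elsewhere (17). Its difference was 3.41 ± 1.78 (0.111) as named and 6.00 ± 0.91 (4.81e-05) with cluster 27 kept, a test chosen after the data were seen. That of Egr3 went from -1.98 (0.0489) to -0.68 ± 0.82 (0.549), and 29 pairs differed either way.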

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

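The tests of the low immediate early genes in YC libraries were chosen only after that result was seen, and those of the other 2 patterns before. A library far from the rest of its group was looked for in 263 groups of 4 to 6 libraries, and 21 were found, where chance gives about 1 in 20. In OC, OC 4 had 14.2% dendritic cells (next 6.89%), and OC 5 and OC 6 were lowest for endothelial Adam23 (9.24 log2 CPM, next 9.68) and Lhx6 (2.77, next 4.58). In OC phagocytes OC 3 was highest for Aqp1 (5.45, next 4.33) and Ptprb (6.95, next 5.27), and OC 2 for Madd (6.68, next 6.23). In OF, OF 2 had 204747 CPM of Hbb-bs (next 63559) and was highest for Hbb-bs (10.54, next 9.76) and Aqp1 (3.21, next 1.43) in phagocytes and for Mup3 in cholangiocytes (2.51, next 0.54). OF 5 was lowest for endothelial Adam23 (4.44, next 6.61), OF 4 highest for mesenchymal Colec10 (2.52, next 1.35) and Fcna (2.77, next 1.35), and OF 1 lowest for mesenchymal Il6 (6.92, next 7.79). In YF, YF 2 had 4.63% hepatocytes (next 0.635%) and YF 1 5.86% phagocytes (next 8.49%). YF 1b was lowest for endothelial Emp1 (-0.54, next 3.57) and Igfbp3 (-0.67, next 3.75) (1.68 and -0.60 with vessel cluster 27 of label set 2 kept) and for Cxcl2 in phagocytes (8.84, next 10.69). In phagocytes YF 3 was lowest for Ccnt2 (4.91, next 5.18) and YF 1 highest for Hbb-bt (7.45, next 3.03).

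The effect of enrichment differed between old and young mice by a test of the difference itself in 29 of 46 gene and class pairs, picked for a large change in at least 1 of the 2 comparisons. Over all genes it differed as given above. In log2 units, old minus young, it was in T and NK cells -1.13 for Fam78a, -7.03 for Fos, -5.68 for Fosb, -1.29 for Mitd1, -4.45 for Nr4a2, 0.79 for Tomm5 and -0.71 for Zfp512. In cholangiocytes it was -3.53 for Atf3, -1.18 for Clec2d, -4.57 for Fosb, 6.99 for Sprr1a and, of endothelial genes, -7.28 for Dnase1l3, -5.66 for Kdr and -6.76 for Ptprb. In endothelial cells it was -2.83 for Adam23, -3.15 for Cntfr, -1.98 for Egr3 (-0.68, not called, with cluster 27 kept), -2.87 for Fosb, 6.61 for Nts and -2.72 for Slc40a1. In phagocytes it was -4.37 for Aqp1, 1.12 for Ccnt2, -5.94 for Clec4g, -4.75 for Cxcl2, -4.68 for Fosb, 4.70 for Hba-a1, 5.38 for Hbb-bs, 6.57 for Hbb-bt and -6.10 for Ptprb. Barcodes that no comparison uses held a mean of 175749 CPM of Hbb-bs in OF and 3223 CPM in OC.

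For each count of called genes 10 to 35 splits of the same libraries were fitted. In 16 of 18 tests only the real one of 30 or 35 called as many, too few splits to exclude chance. Real counts and the highest of the other splits were in OF against OC 1171 and 7 for cholangiocytes, 4869 and 2620 for endothelial cells, 2157 and 257 for phagocytes, and 3573 and 949 for T and NK cells. In YF against YC they were 127 and 14 for cholangiocytes, 313 and 81 for endothelial cells, 591 and 358 for phagocytes, and 1195 and 278 for T and NK cells. In OF against YF they were 2835 and 249 for cholangiocytes, 4779 and 2352 for endothelial cells, 614 and 4 for mesenchymal cells, 2435 and 8 for phagocytes, and 1849 and 1 for T and NK cells. In OC against YC they were 359 and 2 for endothelial cells, 1082 and 4 for phagocytes, and 826 and 2 for T and NK cells. With 3 libraries against 3 there are only 10 splits, too few for this test, with 123 and 41 for mesenchymal cells of YF against YC and 179 and 19 for cholangiocytes of OC against YC. For the number of called lists, over classes that hold all libraries, chance cannot be excluded, with as many in 4 of 30 splits for OF against OC (20, highest other 23), 10 of 35 for YF against YC (23, highest other 27), 5 of 30 for OF against YF (22, highest other 24) and 5 of 30 for OC against YC (22, highest other 22).

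Immediate early and heat shock genes were low in YC libraries. A mix of cell classes does not account for this, since in 5 of 5 classes each YC library lay below each other one measured. Nor does depth per cell, since all 6 libraries no deeper than the deepest YC library lay above the highest YC share. Library batch, as the label set, stays open: YF 1b of the same label set was over 2 times the highest YC library in 5 of 5 classes (3.74 to 6.79 times), but it is 1 library, and set 2 and its diet cannot be told apart from the group in YC. Young age alone does not account for it, since all measured YF libraries lay above YC in each of the 5 classes (means 1.61% against 0.320% in cholangiocytes and 1.48% against 0.320% in phagocytes). Nor does the control digest alone, since all measured OC ones did too (1.46% in phagocytes, and 1.13% against 0.272% in T and NK cells). Young age and the control digest together, which only YC has, were untested and stay open.

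Endothelial genes were lower in phagocytes of OF than of OC. If free RNA of endothelial cells were the source, phagocytes and T and NK cells of a library would hold it alike, and the ratio of their shares had a median of 1.2 over OC libraries (0.497 to 2.22). If endothelial cells or doublets counted as phagocytes were the source, it would gather in few cells, and the top 10% of phagocytes held a median of 1.42 times the share of Poisson draws (1.06 to 1.85). Both ranges cross the bounds set in advance, so neither is excluded and the 2 cannot be told apart. A lower expression in phagocytes themselves was not tested.

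Kupffer cell genes were lower in phagocytes of OF than of OC. More cells of the Monocyte type do not account for this, since in the Macrophage type alone the median change was 1.26 times that of the class, with 9 of 16 genes lower. Hepatocyte free RNA was not excluded, since with its share as a covariate the median was 0.432 times as large (-1.03 from -2.38), with 2 of 16 genes lower and 1040 genes called in all against 2157. The covariate differs between OF and OC, so a loss of Kupffer cells that goes with it was not excluded. Fewer Kupffer cells among the macrophages of OF were not tested and stay open, as cells of OF were few in the Kupffer cluster 10. Both groups are old, so age does not account for the fall, and the enriched niche stays open, untested.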

How the results depend on the processing

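Tests chosen after the data were seen are listed with the alternatives above. Of 106 named gene results 39 kept their call and direction under every alternative run, and 67 lost the call in at least 1. Over all alternatives, 1891 of 2151 values for named genes kept call and direction, 258 lost the call and 2 reversed. Of 438 list values 315 kept both, 93 lost the call, 13 gained one and 17 reversed. Of 590 share values 514 kept both, and of 365 counts of genes 262 stayed within 1.5 times the count reported. The number of differing effects stayed within 1.5 times in all 31 runs. With cluster 27 kept, called endothelial genes were 295 in YF against YC, 4777 in OF against YF and 350 in OC against YC, no share, named gene or list changed its call, and the differences of effects changed for Emp1 (called) and Egr3 (not called). Except where stated, the cause of a change was not tested.

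Counts of called genes that moved by more than 1.5 times follow. With DESeq2 they were in YF against YC cholangiocytes 228, endothelial cells 721 and mesenchymal cells 187, and in OC against YC cholangiocytes 467 and endothelial cells 906. With at least 50 cells per library they were in YF against YC mesenchymal cells 23, and in OF against YF mesenchymal cells 403, and in OC against YC cholangiocytes 319. Without the 5% of cells with the most UMIs they were in OC against YC cholangiocytes 92. With the hepatocyte free RNA covariate they were in OF against OC phagocytes 1040, and in YF against YC phagocytes 380, and in OF against YF mesenchymal cells 97 and phagocytes 452, and in OC against YC phagocytes 100 and T and NK cells 514. With YF of label set 1 alone they were in YF against YC mesenchymal cells 790. In label set 1 alone they were in OF against YF mesenchymal cells 385 and T and NK cells 1172. In label set 2 alone, with YF 1b taken to vary like the libraries of the other groups, they were in YF against YC cholangiocytes 212, phagocytes 167 and T and NK cells 349. With own cluster names they were in OF against YF mesenchymal cells 1676, and in OC against YC cholangiocytes 710 and phagocytes 567. Without the libraries with a code they were in OF against OC phagocytes 1160, and in OC against YC cholangiocytes 71. With OC 1 and 3 as the only OC libraries they were in OF against OC phagocytes 1111 and T and NK cells 2075, and in OC against YC cholangiocytes 319, phagocytes 417 and T and NK cells 207. With the T type alone they were in OF against YF T and NK cells 625. With the dissociation share covariate they were, as given above, in OF against OC 84 and 2797, and in YF against YC 7, 147, 0, 12 and 83. In OF against YF they were 290, 3050 and 30, and in OC against YC 9, 92, 24 and 11. In each of these the share does not overlap between the groups, so lost calls show no cause. Beside the 0 (edgeR), 885 genes had an unadjusted p under 0.05, and DESeq2 without the covariate called 187. Lists called with an estimated correlation were 0 in OF against OC, 11 in YF against YC, 3 in OF against YF and 7 in OC against YC, where the preset correlation gave 26, 29, 28 and 24. The sign reversed for Atf3 in T and NK cells of OC against YC with the dissociation share covariate (-0.01371) and for Plac8 there with own cluster names (0.1257).

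For shares, values are adjusted p from exact permutation tests, or edgeR where named. With edgeR on cell counts, gained calls were in OF against OC hepatocytes 0.044, and in OC against YC mesenchymal cells 0.00659. With own cluster names, lost calls were in OF against OC B cells 0.0662, and uncalled reversals were in OF against YF phagocytes 0.833. Over cells of at least 6624 UMIs, more than most T and NK cells of OF hold, lost calls were in OF against OC T and NK cells 0.812 and B cells 0.0633, and in OF against YF endothelial cells 0.0714 and T and NK cells 0.902, and uncalled reversals were in YF against YC dendritic cells 0.463 and B cells 0.735, and in OF against YF phagocytes 0.268 and B cells 0.952, and in OC against YC dendritic cells 0.976. Some alternatives leave few splits, and a call lost there says nothing on the difference, given in points in brackets. In label set 1 alone p was the smallest 56 splits allow, in OF against YF endothelial cells 0.0804 (-45.6) and T and NK cells 0.0804 (40.1). Without the libraries with a code, OF against OC has 20 splits and no p under 0.1, and OF against YF 35 splits, each p here the smallest. Values were in OF against OC cholangiocytes 0.15 (12.8), endothelial cells 0.15 (-29.6), mesenchymal cells 0.15 (6.33), T and NK cells 0.15 (24.6) and B cells 0.15 (-15.7), and in OF against YF endothelial cells 0.0857 (-42.2) and T and NK cells 0.0857 (34.1), and uncalled reversals were in OF against OC phagocytes 1, and in OC against YC dendritic cells 0.6. With OC 1 and 3 as the only OC libraries there are 21 splits and no p under 0.0476. Values were in OF against OC cholangiocytes 0.161 (10.2), endothelial cells 0.107 (-27.4), mesenchymal cells 0.161 (4.87), T and NK cells 0.107 (38.5) and B cells 0.107 (-15), and uncalled reversals were in OF against OC hepatocytes 0.809, and in OC against YC hepatocytes 0.7, phagocytes 0.7 and neutrophils 0.54. In label set 2 alone, where 1 YF library allows no test, the YF minus YC difference was endothelial cells -4.89 and dendritic cells 4.9 points.

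Without each library in turn, genes called ranged as follows, moved meaning by more than 1.5 times. In OF against OC they were cholangiocytes 811 to 1290, endothelial cells 4178 to 5170, phagocytes 1571 to 2303 and T and NK cells 2877 to 3974. In YF against YC they were cholangiocytes 25 to 131 (moved without YC 1, YC 2 and YC 3), endothelial cells 145 to 330 (moved without YC 1, YC 2 and YC 3), mesenchymal cells 62 to 790 (moved without YF 1, YC 1, YC 2, YC 3 and YF 1b), phagocytes 328 to 755 (moved without YC 2 and YC 3) and T and NK cells 584 to 1155 (moved without YF 1, YC 1, YC 2 and YC 3). In OF against YF they were cholangiocytes 2061 to 3449, endothelial cells 4082 to 5153, mesenchymal cells 287 to 850 (moved without OF 1, OF 5 and YF 1b), phagocytes 1768 to 2586 and T and NK cells 1172 to 2696 (moved without OF 3, YF 3 and YF 1b). In OC against YC they were cholangiocytes 13 to 319 (moved without OC 1, OC 3, OC 6, YC 1, YC 2 and YC 3), endothelial cells 100 to 554 (moved without OC 1, OC 3, YC 1, YC 2 and YC 3), phagocytes 275 to 1304 (moved without YC 2 and YC 3) and T and NK cells 235 to 999 (moved without OC 2, OC 5, YC 1, YC 2 and YC 3). Adjusted p of the shares that changed a call or sign ranged in OF against OC over dendritic cells 0.0143 to 0.357, neutrophils 0.405 to 0.968 and B cells 0.0143 to 0.0686, in YF against YC over hepatocytes 0.675 to 1 and dendritic cells 0.45 to 1, in OF against YF over hepatocytes 0.298 to 0.8286, endothelial cells 0.0536 to 0.129 and T and NK cells 0.0536 to 0.129, in OC against YC over phagocytes 0.522 to 1 and dendritic cells 0.522 to 0.964. The endothelial and T and NK calls of OF against YF were lost without any 1 library, where p was the smallest possible in each run but did not pass after adjustment. Dendritic cells gained a call without OC 4. Signs without a call turned for neutrophils of OF against OC without OC 3, hepatocytes of YF against YC (0.675) and OF against YF (0.703) without YF 2, dendritic cells of YF against YC without YF 1b (1) and of OC against YC without OC 4 (0.522), and phagocytes of OC against YC without OC 5 (0.964) or OC 6 (1).

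The labels give the groups the same replicate numbers. In none of the 14 comparisons by class with 3 or more same-numbered pairs did the deviations of all pairs correlate above 0.1, or all correlate best with their own number (r -0.36 to 0.26 over all 18, with both of 2 pairs above 0.1 in cholangiocytes of OF against OC), so the numbers were not taken to pair the libraries. With the replicate block, which uses only libraries whose number both groups hold, genes called were in OF against OC endothelial cells 2617, phagocytes 1269 and T and NK cells 2002, and in YF against YC cholangiocytes 248, endothelial cells 622, mesenchymal cells 598, phagocytes 377 and T and NK cells 1920, and in OF against YF cholangiocytes 1378, endothelial cells 1982, mesenchymal cells 185, phagocytes 669 and T and NK cells 94, and in OC against YC endothelial cells 37, phagocytes 517 and T and NK cells 180, and in the other 2 tests the count stayed within 1.5 times. Under it no share could be called, as 5 pairs of OF against OC give no p under 0.0625 and 3 of OF against YF none under 0.25. Adjusted p (difference in points) were in OF against OC cholangiocytes 0.113 (10.5), endothelial cells 0.113 (-29.5), mesenchymal cells 0.113 (4.99), T and NK cells 0.113 (33) and B cells 0.113 (-13.5), and in OF against YF endothelial cells 0.75 (-46.6) and T and NK cells 0.75 (46), and uncalled reversals were in YF against YC dendritic cells 1, and in OF against YF cholangiocytes 1, and in OC against YC neutrophils 1. List signs turned under the block (adjusted p). They were in OF against OC effector and exhaustion in T and NK cells 0.893, in YF against YC cell cycle in cholangiocytes 0.789, interferon response in endothelial cells 0.725, stellate quiescence in mesenchymal cells 0.764, hepatocyte free RNA in mesenchymal cells 0.789, erythroid in phagocytes 0.303 and mitochondrial in phagocytes 0.788, in OF against YF cell cycle in cholangiocytes 0.848, fibrillar matrix in mesenchymal cells 0.0089, portal fibroblast in mesenchymal cells 0.024 and cell cycle in T and NK cells 0.775, in OC against YC hepatocyte free RNA in cholangiocytes 4.27e-04, Kupffer genes in endothelial cells 0.191, mitochondrial in endothelial cells 0.217 and erythroid in T and NK cells 0.831, and in label set 1 alone in OF against YF fibrillar matrix in mesenchymal cells 0.342 and portal fibroblast in mesenchymal cells 0.342.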

Other observations

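The genes and values in this part were chosen after the results were seen. Endothelial interferon response was not called as a list in OF against OC (6 higher and 2 lower of 19, adjusted p = 0.357). Ifi27l2a rose by 2.87 ± 0.56 (edgeR adjusted p = 8.1e-04), Ly6e by 1.37 ± 0.19 (1.06e-05) and the GTPase gene Gbp2 by 1.09 ± 0.26 (0.00289), while Ifit2 fell by 1.66 ± 0.35 (9.47e-04). Against YF, also not called (4 higher and 2 lower of 19, 0.6575), members were Ifi27l2a (2.31 ± 0.60, 0.00694), Ly6e (1.10 ± 0.22, 5.19e-04) and Ifit2 (-1.59 ± 0.36, 0.00230), while the membrane protein gene Bst2 fell by 0.94 ± 0.23 (0.00355). Endothelial cell cycle was not called either (4 higher and 1 lower of 16, 0.598), and of its members Pcna rose by 1.21 ± 0.16 (5.99e-06), Stmn1 by 1.42 ± 0.23 (4.43e-05) and the thymidylate synthase gene Tyms by 1.51 ± 0.26 (9.2e-05) in OF against OC, and the replication helicase gene Mcm3 fell by 0.63 ± 0.13 (4.92e-04).

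Mitochondrial transcripts were 4.61% ± 1.92 of all UMIs in OF, 8.33% ± 3.58 in OC, 12.7% ± 6.00 in YF and 21.4% ± 4.50 in YC (mean ± SD of libraries). Alb, from hepatocytes, was at 765 CPM in OC, 1052 CPM in OF, 1186 CPM in YC and 1232 CPM in YF. Own clusters with an erythroid name held 1087 cells that the authors call T or NK cells and 391 that they call endothelial.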
